A study of Triticum aestivum with 18 samples.

How the data were processed

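Poly(A) RNA of whole leaves was measured in 18 wheat libraries, 3 for each of 2 lines under 3 conditions. Per the labels' protocols, the libraries came from a TruSeq kit that does not mark strand and were sequenced as read pairs of 101 nt. Per the submitters' processing notes, the tools were Trim Galore 0.2.8, kallisto with no version given, and sleuth 0.44.0. The estimated counts were made by the authors with kallisto for each library on its own, per the file headers, over 133745 targets, and are not normalized. The deposited TPM values, per the file headers, are kallisto's length-scaled abundances over the same targets. Target and effective lengths stand beside them. The genome build and annotation are not given in the sources used here. Between 23.1% and 25.0% of the estimated counts above 0 in a library were exactly whole as deposited, with no tolerance, and fractional values arise where targets share reads. Wheat carries A, B and D copies of most genes, and counts of near-identical copies are uncertain for that reason. Strand was not marked, so reads of a gene and of an overlapping antisense gene cannot be told apart.

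Groups and replicate numbers were taken from the sample labels. Estimated counts were summed over the targets of each gene identifier, 16961 of 107891 of which have more than 1 target, and rounded to whole numbers. The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors, its default filter on low counts by group, 1 model of the 6 group means over all libraries, and Benjamini-Hochberg adjustment, with calls at an adjusted p of 0.05. Of all identifiers 59084 were tested. The same model gave the treatment effects in each line, the line effects in each condition and the interactions. Standard errors of log2 fold changes were computed from the fold change and its test statistic. CPM values use TMM-scaled library sizes. Counts of expressed genes use the deposited TPM at a minimum of 1.

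Genes were named by a rule written before the data were examined, as were the groups, the tests and the other settings except those named below. It takes, per contrast, the largest rises and falls among called genes with a mean log2 CPM of at least 1 over all libraries, at most 2 each way because nothing pairs the identifiers with names. In the comparisons of 2 groups the libraries of the groups must not overlap, which the rule does not ask of an interaction. A gene without counts in the lower group has a bound computed against 3 counts over the group. With 1 to 3 counts there, a ratio with a 95% exact interval is given instead. A bound takes the mean CPM of the higher group as exact and leaves out its counting error. The words "at least" are therefore approximate where the higher group holds few counts. Intervals cover counting error only. The table of reference genes, of the assembly IWGSC CS RefSeq v2.1, matched 0 of the identifiers, so the planned tests of gene lists could not be run. The transgene target is 1392 nt long.

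Called genes on each chromosome and subgenome were compared with all other tested genes by Fisher's exact test, two-sided, adjusted over all 9 contrasts together. Sets of genes called in 1 contrast were tested in another that shares no library with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one. For contrasts that share control libraries, groups without effect were simulated 10 times against those controls. The drought responses of both lines were also simulated 10 times from equal WWC levels. The test was tried on simulated counts for ox WWC against null WWC over 55601 genes: it recovered 14 of 50 genes changed 1.25-fold, 31 of 50 at 1.5-fold, 41 of 50 at 2-fold and 49 of 50 at 4-fold, with 19 false calls among 154. Replicates of each group differed by more than sampling noise, with a mean chi-square per gene of at least 1.27, and none was taken as a repeat of another. Such a spread does not show whether the replicates came from separate plants. The series text describes the replicates as biological.

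The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom, no low-count filter, a filter of 1 CPM in 3 libraries, kallisto targets in place of genes, only the groups of a contrast, the replicate number as a block, and each library left out in turn. Library totals without TMM factors, and leaving out chromosome 6B, were added after the data were seen. Because TMM factors ran from 0.871 to 1.14 and differed between groups, the direction split under library totals is printed beside each count where it moved by more than 10 percentage points.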

Results

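Poly(A) RNA from whole wheat leaves was sequenced in 18 libraries, 3 in each of 6 groups. The groups crossed 2 genotypes with 3 conditions. One genotype was the bread wheat cultivar Fielder without a transgene (called null here), and the other was a transgenic line in the same background that overexpresses a wheat PYL protein, a member of the receptor family for the stress hormone abscisic acid (ABA), called ox here. The well-watered control plants (WWC) received a 0.05% Tween20 spray and stood at a soil water potential above -110 kPa. The ABA plants were sprayed with 25 µM ABA, and the drought plants were kept below -390 kPa and under 8% water content. Leaves were taken after 24 h, and whether the drought plants were sprayed is not given in the sources used here. The series text describes biological replicates, and the sources disagree on plant age, given as 32 days after sowing and as 40 days. Between 33106695 and 41339323 estimated read counts were assigned per library over 107891 gene identifiers, of which 59084 passed the low-count filter. Replicates lay close together, with a biological coefficient of variation of 4.24% over all groups, from 3.0% in null WWC to 6.33% in ox drought. This spread within groups, on which the tests rest, does not show whether the replicates of a group came from separate plants. The files do not pair the gene identifiers with names, so at most 2 identifiers that rose and 2 that fell are named per comparison, and functions are not given.

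The number of genes at or above 1 TPM was lowest in null WWC leaves, at 38877 ± 42 (SD, n = 3), and highest in ox ABA leaves, at 43516 ± 242 (SD, n = 3). After ABA the count was higher by 2442 in the null line and by 3235 in the ox line, and under drought by 2044 and 1086. Ox leaves had 1404 more than null leaves under WWC and 2198 more after ABA. Each of these 6 differences had an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow, and the 447 more in ox than in null under drought had a p of 0.2. The deposited TPM carry no TMM factors, which were likewise lowest in null WWC and highest in ox ABA. How far these differences in gene number depend on the scaling was not tested. The 10 most abundant genes took 9.19% ± 0.149 of all counts in null WWC, the highest of the 6 groups, and 4.87% ± 0.0526 in ox ABA, the lowest (SD, n = 3 each). This share differed in each of the 7 comparisons of treatment or line with the same p of 0.1. The first principal component of log2 CPM, with 36.0% of the variance, separated ox ABA from null WWC at its ends, and the second, with 21.7%, separated drought from ABA.

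**Figure D1:**
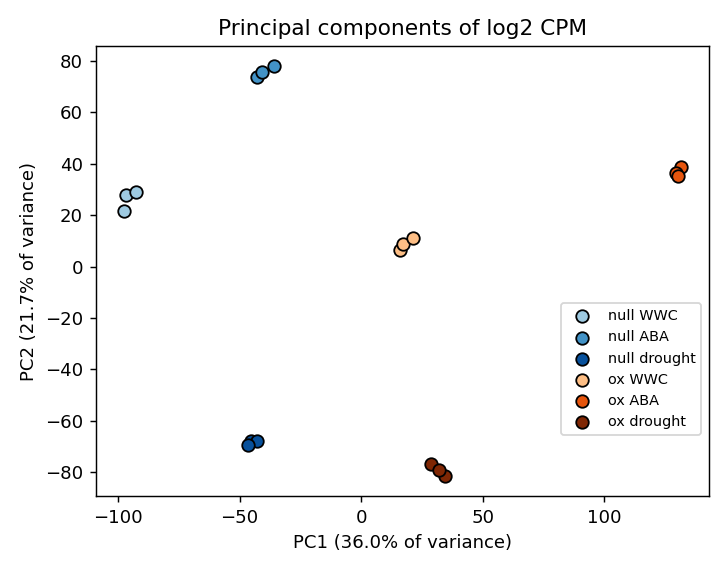
The first 2 principal components of log2 CPM are plotted for the 18 libraries, 1 point per library, coloured by group, with 36.0% and 21.7% of the variance on the axes. Replicates cluster by group, null WWC at the left, ox ABA at the right and both drought groups at the bottom.

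The transgene transcript, listed as synTaPYL1a_GFP and 1392 nt long, was abundant in all 9 ox libraries. It stood at 283 ± 4.67 TPM in ox WWC, 485 ± 18.7 TPM in ox ABA and 295 ± 6.9 TPM in ox drought (SD, n = 3 each). The 9 null libraries held 51 counts of it in all, 36 of them in null drought replicate 1 and 11 in null ABA replicate 1, against 10835 or more in every ox library. Within the ox line it rose with ABA by 0.45 on the log2 scale (SE 0.0881, adjusted p = 7.79e-05, edgeR quasi-likelihood test) and did not pass the test with drought (log2 fold change -0.08, SE 0.0884, adjusted p = 0.503). The size of the ABA rise depended on the scaling, at 0.71 with library totals alone (adjusted p = 9.01e-09) and 0.78 from the deposited TPM. The DESeq2 Wald test did not call it (log2 fold change 0.44, adjusted p = 0.839).

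**Figure D2:**
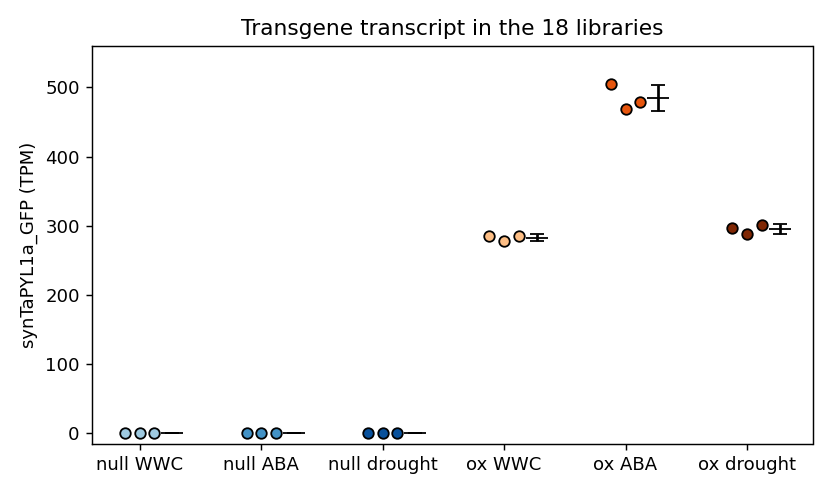
The abundance of synTaPYL1a_GFP in TPM is plotted per library (points) for the 6 groups, with the mean and SD (n = 3) beside them. Ox libraries lie between 277.4 and 505.6 TPM, highest after ABA, and the null libraries lie below 1 TPM.

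In the null line, ABA changed close to as many genes up as down, and the larger changes were mostly rises. A total of 9782 genes rose and 9245 fell, and changes over 2-fold comprised 2192 rises and 825 falls. TraesCS6A02G067500 went from 1 count over the WWC libraries to 4.12 ± 0.503 CPM (SD, n = 3), a ratio of 435 with a 95% counting interval of 77.6 to 17200 (adjusted p = 2.47e-18). TraesCS2A02G476700, without a count in WWC, reached 0.945 ± 0.138 CPM, at least 33.1-fold higher (adjusted p = 4.68e-08). TraesCS6D02G206200 fell from 2.69 ± 1.74 to 0.0799 ± 0.0301 CPM (adjusted p = 5.95e-07), and TraesCS2A02G034500 from 0.0873 ± 0.0552 CPM to no count, at least 3.31-fold lower (adjusted p = 0.00335). The fall of TraesCS2A02G034500 rested on 9 counts over the null WWC libraries. That gene met the minimum mean log2 CPM through the ox groups, where it stood at 12.8 to 18.5 CPM. Without null WWC replicate 2, which held the single count of TraesCS6A02G067500, the log2 fold change of TraesCS6D02G206200 went from -5.03 to -4.35, and without replicate 3 the adjusted p of TraesCS2A02G034500 was 0.0272. Calls are from the edgeR quasi-likelihood test at an adjusted p of 0.05. The direction split depended on scaling: 51.4% of called genes were higher with TMM factors and 86.1% when libraries were scaled by their totals alone, which moved the median of all genes by 0.24 on the log2 scale.

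Drought in the null line lowered more genes than it raised with TMM factors, 10896 against 9402, and raised more with library totals alone. It gave 2420 rises and 1995 falls over 2-fold. TraesCS3B02G336300, without a count in WWC, reached 2.45 ± 0.282 CPM (SD, n = 3), at least 85.9-fold higher (adjusted p = 1.89e-16), and TraesCS6B02G383500 reached 1.87 ± 1.04 CPM, at least 65.7-fold higher (adjusted p = 3.17e-11). TraesCS2A02G107600 fell from 0.161 ± 0.00901 CPM, or 17 counts over the WWC libraries, to no count. It was at least 6.37-fold lower (adjusted p = 2.85e-05, edgeR quasi-likelihood test), while the same gene stood at 15.2 ± 0.714 CPM after ABA. TraesCS2A02G332700 fell from 4.82 ± 0.425 to 0.20 ± 0.179 CPM (adjusted p = 8.94e-18), with a log2 fold change of -4.55 that was -5.52 without null drought replicate 1. Of the called genes, 46.3% were higher with TMM factors and 77.1% with library totals alone, with the median of all genes moved by 0.18.

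ABA changed more genes in the ox line than in the null line: 14283 rose and 12447 fell, with 3489 rises and 1833 falls over 2-fold. TraesCS5B02G566400 rose from 2 counts over the WWC libraries to 5.53 ± 0.364 CPM (SD, n = 3; ratio 293, 95% counting interval 80.8 to 2420), and TraesCS6A02G067500, also the leading riser in the null line, from 3 counts to 7.86 ± 0.113 CPM (ratio 276, interval 94.3 to 1340). Their adjusted p were 3.66e-20 and 7.77e-22, both WWC counts of the first lay in replicate 3, and without ox WWC replicate 2 the log2 fold change of the second went from 7.95 to 8.84. TraesCS2D02G563600 fell from 129.5 ± 3.97 to 11.9 ± 1.96 CPM (log2 fold change -3.45, SE 0.0859, adjusted p = 5.45e-26) and TraesCS6B02G091400 from 21.6 ± 2.34 to 2.17 ± 0.198 CPM (log2 fold change -3.31, SE 0.105, adjusted p = 3.95e-23). The higher share was 53.4% with TMM factors and 82.1% with library totals alone, with the median of all genes moved by 0.27.

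Drought in the ox line raised 9362 genes and lowered 10509 with TMM factors. Falls outnumbered rises among changes over 2-fold, 2215 to 1398, while library totals alone gave 1816 falls and 1854 rises. TraesCS5A02G392100 rose from 0.0484 ± 0.0358 to 4.18 ± 1.23 CPM (SD, n = 3; adjusted p = 3.9e-16; log2 fold change 6.36, or 7.07 without ox WWC replicate 2) and TraesCS2D02G253900 from 0.143 ± 0.0584 to 8.78 ± 2.86 CPM (adjusted p = 2.4e-17). Counts of TraesCS5D02G488900 went from 0.718 ± 0.191 CPM to none, at least 25.8-fold lower (adjusted p = 3.91e-07), and those of TraesCS2A02G107600 from 0.379 ± 0.0391 CPM to none, at least 13.6-fold lower (adjusted p = 5.89e-08). The higher share was 47.1% with TMM factors and 69.2% with library totals alone, with the median of all genes moved by 0.12.

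**Figure D3:**
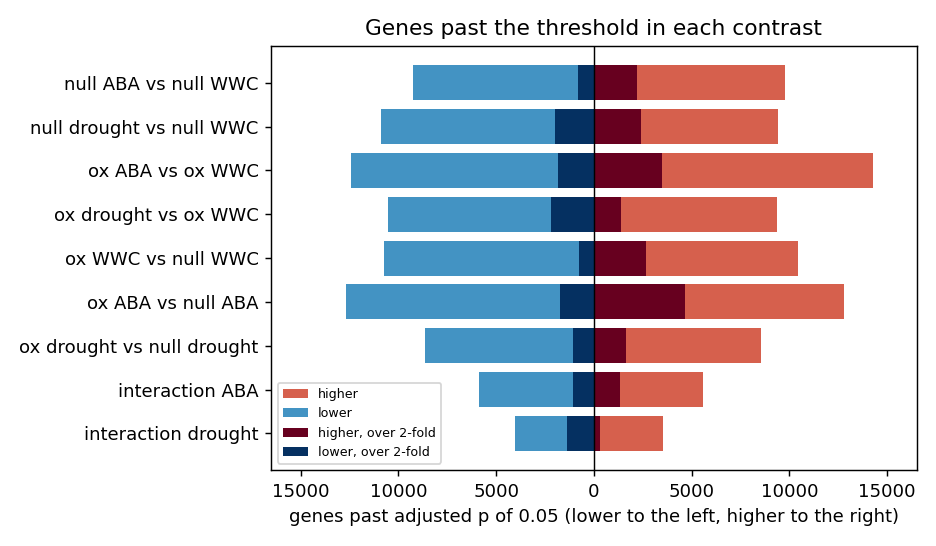
The horizontal axis counts genes past an adjusted p of 0.05 in each of 9 contrasts, lower to the left and higher to the right, with changes over 2-fold in the darker colour. ABA in the ox line and the ox to null difference after ABA hold the most genes, with 14283 and 12783 higher.

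ABA and drought changed many genes in the same direction. In the null line 10888 genes were called in both responses, 3405 up in both and 5432 down in both, against 1557 and 1705 for independent lists of those lengths. In the ox line 5275 were up in both and 5773 down in both, against 2263 and 2214. With library totals alone the null line's 8837 shared calls of 1 direction became 15073. Opposite directions were also found: 1456 genes rose with ABA and fell with drought in the null line and 595 did the reverse, fewer than the 1804 and 1471 for independent lists. In both lines 423 genes rose with ABA and fell with drought, and 118 did the reverse. In all 4 responses 1962 genes rose and 3113 fell. The 2 responses of a line share their WWC libraries: the covariance of fold changes across the 35546 genes with a mean log2 CPM of 1 or more was 0.0857 in the null line against a simulated 0.0047 with no effect, and 0.10 in the ox line. No gene was called in both in that simulation. Hardly any gene can be called without an effect, so this does not measure the shared calls that common libraries add. Correlations across genes were 0.357 and 0.408, below the 0.518 that the shared libraries gave in the simulation with no effect, and genes are not independent replicates. With 3 WWC libraries per line the controls could not be split with at least 2 on each side, so part of the excess may come from the shared libraries.

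Genes that answered a treatment in one line mostly moved the same way in the other. Among genes called for ABA in the null line, 85.5% had the same sign in the ox line with a median ox to null ratio of 0.864, and among genes called in the ox line the null to ox ratio was 0.492. Selecting genes in one line shrinks the other, so both ratios would lie below 1 even for equal responses, and by the comparison of these medians the ABA response was the larger in ox. For drought the ratios were 0.619 for genes called in null and 0.711 for genes called in ox, and which line had the larger response then depended on the direction of change. Of the 2420 genes that rose over 2-fold with drought in null, 1403 were called up in ox and 197 down, with a median of 1.60 in null and 0.77 in ox on the log2 scale. The 1398 that rose over 2-fold in ox had 1.43 in ox and 1.49 in null. Of the 1995 that fell over 2-fold in null, 1436 were called down in ox and 12 up, with medians of -1.49 in null and -1.14 in ox. The 2215 that fell over 2-fold in ox had -1.53 in ox and -1.03 in null. The differences between these ratios and medians were not tested. The responses of the 2 lines share no library.

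The ABA response differed between the lines at 11447 genes, 5556 with a higher and 5891 with a lower change in ox. Which direction held more genes turned without chromosome 6B, with 5486 higher and 5141 lower, and with library totals alone, with 6098 higher and 5302 lower. Of the 11447, 2722 moved the same way in both lines and further in ox, 684 the same way and further in null, and 1065 in opposite directions, all with both responses called. A further 2633 rose and 2188 fell with only the ox response called, and 1070 rose and 801 fell with only the null response called. TraesCS6D02G206200 fell with ABA in null, as above, and went from 1.30 ± 0.297 to 31.1 ± 12.2 CPM (SD, n = 3) in ox (interaction log2 9.59, or 8.90 without null WWC replicate 2, SE 0.682, adjusted p = 1.28e-12). TraesCS2A02G107600 rose in null from 0.161 ± 0.00901 to 15.2 ± 0.714 CPM and in ox from 0.379 ± 0.0391 to 1.18 ± 0.196 CPM (interaction log2 -4.89, SE 0.379, adjusted p = 5.8e-11), and TraesCS2B02G125200 rose from 0.103 ± 0.055 to 9.51 ± 2.46 CPM in null and from 0.268 ± 0.119 to 1.90 ± 0.242 CPM in ox (adjusted p = 3.03e-05). The rule for named genes also took TraesCS6A02G132500, whose call (adjusted p = 0.03) rested on 106 null WWC counts at 0.988 ± 1.71 CPM, against none in null ABA, and on levels of 5.13 ± 3.72 and 6.64 ± 1.97 CPM in ox WWC and ox ABA. Its adjusted p was 1 without null WWC replicate 2 and 0.0684, 0.07 and 0.08 without null ABA replicates 1, 2 and 3, and over the other settings it ran from 2.74e-34 to 0.456, the last with limma-voom.

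The drought response differed between the lines at 7571 genes, 3550 with a higher and 4021 with a lower change in ox, and the larger differences were mostly of the second kind, 1389 against 312 over 2-fold. Those 1389 genes had a median of 1.28 in the null response, with 1039 called up and 71 down, and of -0.50 in the ox response on the log2 scale, with 287 called up and 668 down. Their median difference of ox from null under WWC was 1.18, with 1098 called higher. The interaction contains that difference with the opposite sign, and in simulations with equal WWC levels such genes had a median of 0.11 with at most 2 called higher. The simulations held 2125 to 2214 such genes, more than the data, so they are not the same set of genes. TraesCS1B02G468400 stood at 3.53 ± 3.37 CPM in null WWC, 2.13 ± 2.98 in null drought, 1.22 ± 0.101 in ox WWC and 17.4 ± 6.19 in ox drought (SD, n = 3 each; interaction log2 4.60, SE 0.79, adjusted p = 6.2e-05), and its interaction was 6.93 without null drought replicate 3 and 3.50 without null WWC replicate 2. TraesCS3D02G332200 rose in ox from 1.14 ± 0.299 to 7.92 ± 0.0993 CPM and stood at 2.28 ± 0.297 and 2.22 ± 0.235 CPM in null (interaction log2 2.83, SE 0.227, adjusted p = 2.2e-11). TraesCS7A02G176400 went from 0.186 ± 0.187 to 5.58 ± 0.837 CPM with drought in null and from 1.83 ± 0.43 to 0.847 ± 0.0799 CPM in ox (interaction log2 -6.03, or -7.13 without null WWC replicate 3, SE 0.391, adjusted p = 1.44e-13). TraesCS6D02G332900, at 1.83 ± 2.09 CPM in null drought and without a count in null WWC, passed with an adjusted p of 0.0405. It did not pass without any one of the null WWC replicates, any one of the ox WWC replicates or ox drought replicate 3, with adjusted p from 0.0571 to 0.138, and over the other settings it ran from 5.51e-10 to 0.127. The share of called interactions higher in ox was 46.9% with TMM factors and 31.5% with library totals alone.

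Under well-watered conditions the 2 lines differed at 21204 genes, 10459 higher and 10745 lower in ox, and the differences over 2-fold were mostly higher in ox, 2689 against 759. TraesCS7A02G510200 had no count in null WWC and 17.4 ± 0.795 CPM (SD, n = 3) in ox WWC, at least 608-fold higher (adjusted p = 6.98e-25), and TraesCS4D02G238700 had none and 13.8 ± 2.18 CPM, at least 484-fold higher (adjusted p = 1.88e-22). TraesCS1B02G275200 was lower in ox, at 1.91 ± 0.181 against 18.4 ± 0.741 CPM (log2 fold change -3.26, SE 0.0929, adjusted p = 2.36e-24), as was TraesCS6B02G090800, at 0.0862 ± 0.0774 against 0.754 ± 0.393 CPM (log2 fold change -3.07, or -3.67 without ox WWC replicate 2, adjusted p = 7.18e-06). The higher share was 49.3% with TMM factors and 71.3% with library totals alone, with the median of all genes moved by 0.12.

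After ABA the lines differed at 25478 genes, 12783 higher and 12695 lower in ox, with 4642 higher and 1743 lower over 2-fold. TraesCS4A02G431400 had no count in null ABA and 48.7 ± 4.83 CPM (SD, n = 3) in ox ABA, at least 1850-fold higher (adjusted p = 5.31e-28). TraesCS7D02G053800 had 2 counts over the null ABA libraries and 195 ± 8.91 CPM in ox ABA, a ratio of 11100 with a 95% counting interval of 3070 to 91600 (adjusted p = 3.12e-33). TraesCS2A02G107600 was lower in ox, at 1.18 ± 0.196 against 15.2 ± 0.714 CPM (adjusted p = 5.69e-22), as was TraesCS7B02G129700, at 1.02 ± 0.198 against 8.29 ± 0.682 CPM (adjusted p = 1.11e-18). The higher share was 50.2% with TMM factors and 71.7% with library totals alone, with the median of all genes moved by 0.14.

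Under drought 8545 genes were higher and 8636 lower in ox (8264 and 7890 without chromosome 6B), the fewest of the 3 comparisons between lines, with 1651 higher and 1048 lower over 2-fold. TraesCS5B02G220300 and TraesCS7A02G506300 had no count in any null library and stood at 8.69 ± 0.608 and 7.49 ± 0.643 CPM (SD, n = 3) in ox drought, at least 343-fold and 296-fold higher (adjusted p = 6.57e-21 and 2.29e-19). TraesCS5D02G488900 had no count in ox drought and 0.134 ± 0.0616 CPM, or 16 counts over the libraries, in null drought. It was at least 4.82-fold lower (adjusted p = 0.0112, edgeR quasi-likelihood test). TraesCS5B02G390900 was lower in ox, at 0.0541 ± 0.0937 against 1.01 ± 0.46 CPM (adjusted p = 2.1e-05, same test). All 6 ox counts of TraesCS5B02G390900 lay in replicate 1, and its fitted log2 fold change went from -4.09 to -8.25 without that replicate. The higher share was 49.7% with TMM factors and 62.8% with library totals alone. In all 3 conditions 3007 genes were higher and 3582 lower in ox, and 829 and 173 of these by over 2-fold. Another 1417 genes were called in all 3 conditions with mixed directions.

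Across treatments, the difference between the lines ran in the direction of the null line's own stress responses. Genes that rose with drought in null were higher in ox than in null after ABA, with a median of 0.32 on the log2 scale (5174 called higher and 716 lower of 9402), and genes that fell were lower, with a median of -0.24 (1280 called higher and 5848 lower of 10896). Genes that rose with ABA in null had a median of 0.11 in the difference under drought (2897 called higher and 1053 lower of 9782), and genes that fell had -0.10 (1081 and 3107 of 9245), or -0.05 with library totals alone. These pairs of contrasts share no library. In camera set tests added after the data were seen, adjusted p with an estimated correlation were 2.02e-07 for both drought sets and 0.000772 for both ABA sets, and all 4 also passed with the preset correlation. Within a treatment the pattern differed. For the ABA sets the difference after ABA had medians of 0.08 and -0.18, while for the drought sets the difference under drought had -0.06 and 0.01, and these contrasts share the treated null libraries, which pull such medians the opposite way. Under WWC, where the null control libraries are shared, the medians were 0.21 and -0.20 for the ABA sets and 0.19 and -0.15 for the drought sets, against simulated values with no difference between lines of 0.02, -0.02, 0.02 and -0.02. With library totals alone the WWC medians of the genes that fell were -0.09 and -0.05.

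Chromosome 6B stood apart from the other 20 chromosomes in every contrast that included the ox line. Of its 2407 tested genes, 49.5% were called between the lines under WWC against 35.3% of the genes of other chromosomes (odds ratio 1.8, adjusted p = 2.89e-42, Fisher's exact test), 52.2% against 42.7% after ABA (odds ratio 1.47, adjusted p = 2.56e-18) and 42.7% against 28.5% under drought (odds ratio 1.87, adjusted p = 2.37e-45). In the ABA interaction the odds ratio was 2.25 (adjusted p = 1.41e-65), with 70 genes higher and 750 lower, and in the drought interaction 1.85 (adjusted p = 1.04e-27), with 43 higher and 460 lower. In the ox responses to ABA and drought it was 1.41 and 1.43 (adjusted p = 9.35e-15 and 1.43e-15). Its median log2 fold change was 0.10 in ox against null under WWC, -0.25 after ABA and -0.12 under drought, outside the -0.07 to 0.04 spanned by the other 20 chromosomes in these contrasts. In the null responses to ABA and drought the 6B medians were -0.01 and 0.00 and the odds ratios 0.932 and 0.909 (adjusted p = 0.294 and 0.125, the second passing without the low-count filter). The medians furthest from 0 in the null response to ABA were those of 1A and 6A: 1A had a median of 0.08, with 607 genes called up and 290 down (odds ratio 1.2, adjusted p = 0.000415), and 6A, a homoeologue of 6B, had a median of -0.06, with 305 up and 467 down (odds ratio 1.04, adjusted p = 0.634). The odds ratios of the A, B and D subgenomes lay between 0.891 and 1.11 over the 9 contrasts, and 17 of 27 passed. The lowest adjusted p was 3.02e-06, for B between the lines under drought (odds ratio 1.11). The B subgenome includes 6B. Without 6B genes, a test added after the shift was seen, that odds ratio was 1.02 (adjusted p = 0.375). In that test 15 of 27 passed, with odds ratios between 0.93 and 1.09. Its p were adjusted over these 27 alone, while those with 6B genes were adjusted together with the tests of the chromosomes. The adjusted p and numbers passing with and without 6B are thus not strictly alike. Among the comparisons between lines and the interactions, B passed in 4 with 6B genes and in 1 without them. In the ABA interaction its odds ratio turned from 1.06 (adjusted p = 0.0327) to 0.93 (adjusted p = 0.00684, Fisher's exact test for each). These tests treat genes as independent, which neighbours need not be.

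A search for 1 change point along 6B, in the order of the identifiers and with at least 100 genes on each side, placed 1152 tested genes up to TraesCS6B02G241800 and 1255 after it. This division was chosen after the data were seen, and none or several points were not compared with it. Levels were centred for each gene on its mean over all libraries. They compare the groups with each other and do not give how strongly 6B genes are expressed beside other chromosomes. In the first part, the median log2 level relative to the other chromosomes was 0.18 ± 0.01 in null WWC, 0.16 ± 0.01 in null ABA and 0.18 ± 0.01 in null drought, and -0.04 ± 0.00, -0.23 ± 0.01 and -0.23 ± 0.01 in the same conditions of ox (SD, n = 3 each). In the second part it lay between -0.06 and -0.04 in the 3 null groups and at 0.28 ± 0.01 in ox WWC, -0.15 ± 0.01 in ox ABA and 0.02 ± 0.02 in ox drought. Without chromosome 6B, which was left out after the shift was seen, the calls were 9739 higher and 10273 lower in ox under WWC, 12509 and 11712 after ABA, 8264 and 7890 under drought, 5486 and 5141 in the ABA interaction and 3507 and 3561 in the drought interaction. The direction with more genes turned under drought and in the ABA interaction. If the plants of the ox groups differed in 6B copies, a possibility taken up below, genes of other chromosomes could be affected too. Leaving out 6B genes would not remove such effects. The ox responses, their size relative to null and both interactions therefore cannot be assigned to treatment alone.

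**Figure D4:**
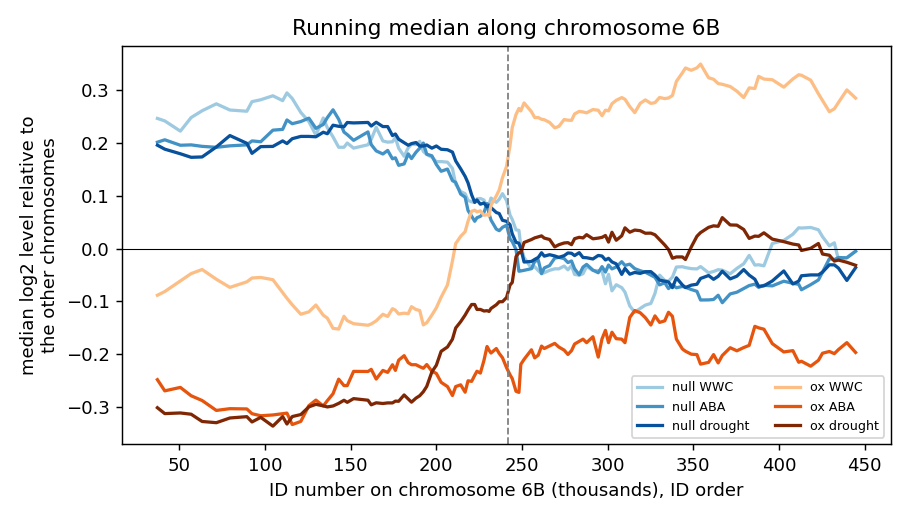
The vertical axis gives the median log2 level of 101 neighbouring genes of chromosome 6B relative to the other chromosomes, centred on the mean of all libraries, and the horizontal axis the number in the gene identifier, in the order of the identifiers. Lines are group means of 3 libraries and the dashed line marks the change point. The 3 null groups run together, while ox WWC lies near 0.28 after the change point and ox ABA stays below 0 along the whole chromosome.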

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

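The splits of the libraries and the test of counts from ox libraries were set before their results were seen, and the division of the interaction splits by whether they kept a line together was chosen only afterwards.

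The ABA response differed between the lines at 11447 genes by the interaction test. Fitted on its 12 libraries alone, it gave 12216 genes, and 1 of 40 splits that reassigned line within condition, the real one, gave as many, with 9888 genes in the highest other. That highest other was among 10 splits that kept the lines together in 1 condition, gave 844 genes or more and carry the difference between lines, so they do not measure chance in the interaction. The 29 that mixed the lines in both conditions gave at most 1, but they hold the difference between lines in the spread of their groups, which may lower the count. This count therefore does not decide whether chance can be excluded.

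The drought response differed between the lines at 7571 genes by the interaction test. Fitted on its 12 libraries alone it gave 7344, and 3 of 40 splits, the real one included, gave as many, with 8351 in the highest other. The 2 others were among 5 splits that kept the lines together in 1 condition and gave 389 genes or more, and the 34 that mixed the lines in both gave 0 genes. For the same reasons this count does not decide whether chance can be excluded.

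For each of the 7 pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05, and 1 of 10, the real one, gave as many genes. The real value and the highest other were 19536 and 0 for ABA in null, 20145 and 0 for drought in null, 26548 and 0 for ABA in ox, 18065 and 0 for drought in ox, 21646 and 1 between lines under WWC, 25048 and 0 after ABA, and 14936 and 1 under drought.

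Counts of the ox transgene appeared in libraries of the null line, 36 in null drought replicate 1 and 11 in null ABA replicate 1, against 0 to 2 in the other 7. RNA or reads from ox libraries in null drought replicate 1 are a candidate source. If so, 5 genes abundant in ox, with at most 1 count each over the null WWC and null ABA libraries, would hold 6.12 counts there in the transgene's proportion, and they held 13, or 212% of the prediction. They also held 7 and 5 counts in null drought replicates 2 and 3, which had 1 and 0 counts of the transgene, so the test leaves the source open.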

How the results depend on the processing

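Library totals without TMM factors, and the counts without chromosome 6B, were chosen only after the results were seen. Of the values that answer a comparison, 224 stayed on their side of the threshold or within 1.5 times or 1 SD of the main value, 52 moved further, 2 passed a threshold that the main value did not pass or crossed 1.5 times, 1 lost a call and 0 reversed. Total numbers of calls are among these values and cannot reverse. The direction that held more called genes is not among them, and it turned in some settings, as given above. With 1 library left out, 182 stayed and 46 moved. Of the values for single genes and subgenomes, 433 stayed, 21 lost and 1 gained a call, and 11 lost one with a library left out. The cause of these moves was not tested, except that leaving out a library leaves fewer samples. The settings kept at least 86.7% of the calls (1 CPM in 3 libraries), 72.4% (library totals alone), 77.3% (DESeq2 Wald test) and 78.4% (a library left out, lowest for the lines under drought without ox drought replicate 2). The replicate number as a block gave 19272 and 20412 calls for ABA and drought in null, 26884 and 20000 in ox, 21354, 25607 and 17436 between lines under WWC, ABA and drought, and 11707 and 7836 interactions, and kept between 98.8% and 99.2% of the calls. Same-numbered libraries correlated from -0.0904 to 0.231 over 45 pairs, and 8 of 18 libraries correlated best with their own number. These values showed no clear pairing by number and do not exclude one. The planned tests of gene lists, with their alternatives, were not run because nothing paired the identifiers with names. At these depths the simulated test recovered 28% of genes at the smallest change tried, 62% at 1.5-fold and 98% at 4-fold under WWC. Few genes were changed in it, and it gave 154 calls, 19 of them false. That false share was above the 0.05 set as the threshold on the adjusted p. The share of false calls in the data was not measured and may also lie above that threshold. With 21204 calls between the lines under WWC, the threshold on the unadjusted p was less strict in the data. Those called genes had a median absolute log2 fold change of 0.44, so the simulated recovery does not carry over to them. Some small changes may still go uncalled.

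With a library left out, calls ran from 16262 to 17152 for ABA in null, 17681 to 18223 for drought in null, 24073 to 24815 for ABA in ox, 17247 to 18155 for drought in ox, 18055 to 18778 between lines under WWC, 23151 to 23824 after ABA, 14220 to 15903 under drought, and 10085 to 10633 and 6329 to 7556 for the ABA and drought interactions.

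With library totals alone the null line shared 15073 calls of 1 direction between ABA and drought. Without the low-count filter the odds ratio of chromosome 6B for drought in null was 0.904 and passed. The ABA rise of the transgene in ox was 0.44 with the DESeq2 Wald test, not called, and 0.78 from the deposited TPM, which gave 0.0625 for drought.

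The ratio of the ABA response in ox over that in null, in genes called in null, was 0.891 with the DESeq2 Wald test, 0.898 with a minimum of 1 CPM and 0.983 with library totals alone, and ran from 0.844 to 0.875 with a library left out. In genes called in ox the ratio of null over ox was 0.501, 0.511 and 0.626 in these settings, 0.474 without the filter and 0.505 without chromosome 6B (0.479 to 0.496 with a library left out). For drought the ratio in genes called in null was 0.629, 0.635 and 0.652, and 0.611 without the filter (0.603 to 0.624), and in genes called in ox it was 0.747, 0.727 and 0.792, 0.70 without the filter and 0.731 without chromosome 6B (0.69 to 0.72).

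The difference under drought in genes that rose with ABA in null was 0.12 with DESeq2 size factors, 0.13 with the Wald test, 0.12 by target and 0.10 with library totals (0.10 to 0.12 with a library left out), and in genes that fell -0.0504 with library totals. After ABA, genes that rose with drought in null had 0.34, 0.40, 0.37 and 0.26 in these settings, 0.29 with a minimum of 1 CPM and 0.34 without the filter (0.31 to 0.35), and genes that fell had -0.23 with size factors, -0.22 with 1 CPM and -0.18 with totals (-0.26 to -0.23). Under WWC, genes that rose with ABA had 0.24 with the Wald test, 0.24 by target, 0.20 with totals and 0.23 without the filter (0.21 to 0.26), and genes that fell had -0.20 with size factors, -0.20 with the Wald test, -0.19 by target, -0.0936 with totals, -0.18 with 1 CPM and -0.21 without the filter (-0.20 to -0.19). Genes that rose with drought had 0.20 with size factors, 0.23 with the Wald test, 0.23 by target, 0.20 with totals, 0.17 with 1 CPM and 0.20 without the filter (0.19 to 0.24), and genes that fell had -0.14 with 1 CPM, -0.0473 with totals and -0.16 without the filter (-0.16 to -0.14).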

Other observations

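The sets of genes and the range on chromosome 7A, the division of chromosome 6B, and the tests of homoeologous copies, of a fixed sequence difference, of common regulation, of 6B copy numbers, of induction and of scattered genes were chosen only after the results were seen.

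Besides the transgene, 28 genes had at most 10 counts over the 9 null libraries and at least 20 in each ox library, and 0 genes showed the converse. Together they held 103 counts in null and 42817 in ox. Among them TraesCS5B02G220300 had 0 null counts and 3055 in ox, and TraesCS7B02G479700 had 9 and 7770. On chromosome 7A there were 8, and 5 of these lay within 50 neighbouring tested genes, between TraesCS7A02G506200 and TraesCS7A02G510200. In that range 13 of 14 tested genes were higher in ox in all 3 conditions. The 14 include the 5 genes, which were chosen for that difference. The 5 genes summed to 33.1 ± 0.537 CPM in ox WWC, 20.7 ± 1.39 in ox ABA and 24.5 ± 0.0449 in ox drought, and to 0.0185 ± 0.016, 0.0171 ± 0.0149 and 0.0752 ± 0.0655 in the same conditions of null (SD, n = 3 each).

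A placement of such genes at random is argued against for this group, since 5 within the window was not reached in 10000 random draws, whose highest was 4 (permutation p = 1e-04, the smallest they can give). Induction through ABA signalling cannot be told apart from a fixed difference between the lines: the null level after ABA and drought was 0.139% of that in ox WWC, but the genes were chosen for low null counts, and that choice allows no more than 0.715%. Reads shared with near-identical copies cannot be told apart from expression: 13.3% of the estimated counts of the 5 genes were whole numbers within 1e-06, under the 50% set beforehand as the mark of sharing, but that mark told nothing, as other 7A genes of like counts, a comparison added after the result was seen, also had 13.3%. A stretch of chromosome that differs between the plants of the 2 lines, in sequence or in presence, may underlie the pattern and was not tested.

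As a source of the shift of chromosome 6B in the ox line, reads that move to the homoeologous copies would raise 6A or 6D where 6B falls, and the medians of 6A and 6D in ox ABA against null ABA were 0.023 and -0.028, below the 0.036 reached among the other 18 chromosomes. Because 6A was itself lower after ABA in null, the ox response was read too, in which the 6A and 6D medians were 0.004 and -0.0003 and that of 6B was -0.29. A fixed sequence difference from the reference, as the only source, would give the same shift in each condition. The ox minus null level ranged over 0.186 before the change point and 0.425 after it. A fixed part beside one that changes with condition is not excluded. Before the change point ox lay below null in all 3 conditions, at -0.22 under WWC, -0.39 after ABA and -0.41 under drought. Regulation by ABA or drought common to both lines is argued against by null 6B medians of 0.003 with drought and -0.006 with ABA. Both lay inside the range of the other chromosomes, whose -0.06 to 0.08 with ABA is set by 6A and 1A and spans -0.02 to 0.03 without them. Different numbers of 6B copies in the plants of the ox groups may underlie the shift and cannot be told apart from regulation of the chromosome in the ox line alone. Of the genes with a mean log2 CPM of 3 or more, 87% after the change point and 73.3% before it were lower in ox ABA than in ox WWC, against 47.3% of such genes elsewhere, but these parts were set from the shift, so the shares restate it, and plants were not genotyped in the files used here.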
